A study of Mus musculus with 14 samples.

How the data were processed

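Cells of the LSK phenotype from the bone marrow of H2B-GFP mice were sorted at 5 GFP levels after 12 weeks of doxycycline, and RNA from 14 sorted samples was amplified, labelled with biotin and hybridised, per the labels' protocols. GCOS, RMA and affy were used, per the submitters' processing notes, which give no versions. The deposited values are log2 probe-set expression, as the values themselves show: they lie between 2.69 and 15.1, with a median of 7.03 over the table. RMA corrects the background, normalizes quantiles and summarizes probes, and no detection calls come with these log2 values. Medians per array lay between 6.96 and 7.18, and interquartile ranges between 2.09 and 2.73, so the arrays still differ in their distributions. Genes were not centred. No genome build is given in the sources used here, so no coordinates are printed. Each column was matched to a sample by its label; 0 columns belonged to no sample.

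The table held 45101 probe sets. By the platform annotation 34958 named exactly 1 gene symbol, 932 named several and 9211 none. Of those with 1 symbol, 34754 matched a gene of the RefSeq table (GRCm38.p6, used for names alone) by gene identifier, and 0 symbols changed. A gene was the probe set with the highest mean over the 14 arrays among those with 1 symbol, which gave 18194 genes; dim probe sets were kept. The 10143 probe sets without a single symbol were not named.

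The values were used as deposited. In limma 3.58.1 (R 4.3.3) a model of group means was fitted to all 14 arrays, with empirical Bayes moderation (9 residual and 3.99 prior degrees of freedom), because 2 groups have only 2 arrays and the groups then share an estimate of the spread. Contrasts were GFP4 against GFP0, the slope per level (equal weight per level), the 4 steps between neighbouring levels, and the difference between the GFP4 and GFP1 steps; moderated F tests covered any difference between levels and the departure from a straight line. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of differences are moderated standard errors, and errors of groups are SDs over arrays.

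Before the data were examined, 25 gene lists were fixed: HSC markers, 3 lists of progenitors, lists of cell cycle phases and regulators, of pathways and processes, of markers of other cells, and of sex-linked genes. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation; of the lists called for GFP4 against GFP0 none held with the estimate, and for the slope HSC markers and multipotent and lymphoid progenitor genes did. Rotation tests (fry) were run beside them, where a list is asked only whether its own genes move. Members were counted over all genes tested and adjusted over the list alone. Genes to be named were also fixed in advance. For GFP4 against GFP0 these were the 10 highest and the 10 lowest folds among genes past the threshold whose arrays did not overlap, whose brighter group mean reached the median of the table and whose probe set did not end in _x_at. For the slope these were the 8 steepest each way under the same conditions, with a Spearman correlation between level and value of at least 0.8 in size. Up to 3 genes each way per step, the 6 genes with the smallest p for the departure, up to 4 members per list and a set of genes by name were added.

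Each fit was tested on simulated arrays with the means and spreads of the 18194 genes and 200 changed genes. For the slope 44.8% of genes changed by 0.25 per level were recovered and 97.0% of those changed by 0.5. For GFP4 against GFP0 40.3% of genes changed by 1 and 91.0% of those changed by 2 were recovered. For GFP4 against GFP3 the shares were 19.4% for a change of 1 and 86.6% for 2, and for GFP1 against GFP0 32.8% and 85.1%. For GFP2 against GFP1 they were 26.9% and 92.5%, and for GFP3 against GFP2 23.9% and 89.6%. With no changed gene, 0 calls were made over all tests. Of the calls made for the slope with changed genes, 6.94% were false. The simulated genes varied independently, unlike real ones. A simulated gene also had the same spread in every array, whereas array quality weights ran from 0.302 to 4.46 in the real arrays. The shares above may therefore be too favourable.

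Alternatives fixed in advance were centring arrays on their medians, cyclic loess, a filter on dim genes, the mean over a gene's probe sets, every probe set by itself, another variance model, array quality weights, the replicate number as a block, leaving out each array, only the arrays of the groups compared, and a regression on the level. Alternatives chosen after seeing the data left out arrays with a narrow spread or a place apart, or added the 3 prime to 5 prime differences of Actb and Gapdh, or the interquartile range of each array, as covariates. Figures were drawn with matplotlib 3.10.9.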

Results

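Expression was measured on 14 Affymetrix arrays in bone marrow cells with the LSK phenotype (no lineage markers, Sca1 and Kit on the surface), the fraction that holds hematopoietic stem cells (HSCs) and multipotent progenitors. The mice carried a histone H2B-GFP fusion gene under a tetracycline-responsive promoter, driven through a human CD34 promoter. Doxycycline, given at 1 mg/ml in the drinking water for 12 weeks from an age of 6 to 8 weeks, stopped the labelling, after which every division diluted the GFP. Cells were sorted into 5 ranked levels, from GFP0 (label most diluted) to GFP4 (label retained), with about 1 to 2 divisions between neighbouring levels. GFP0 had 2 arrays, GFP1 had 3, GFP2 had 3, GFP3 had 2 and GFP4 had 4. The labels call them biological replicates without naming the animals behind each, so p-values measure the spread between these sorted samples. Precision is limited by the number of arrays.

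All values are log2 expression, and differences are log2 differences. Pairs of arrays from the same group correlated with r between 0.928 and 0.990 over 18194 genes, and pairs from different groups with r between 0.911 and 0.990. The first principal component held 27.9% of the variance and the second 24.5%. The interquartile range of all probe-set values was narrowest in GFP0 replicate 1 (2.09) and GFP4 replicate 1 (2.21). GFP4 replicate 2 lay at -68.7 on the third component, while none of the other 13 arrays lay below -8.53. Mean expression of the hybridisation spikes was 10.3 in that array, the highest of the 14. The difference between 3 prime and 5 prime probe sets of Actb, a sign of RNA quality, averaged 4.45 ± 0.09 (SD, n = 2) in GFP0, 3.71 ± 0.19 (SD, n = 3) in GFP2 and 4.64 ± 0.46 (SD, n = 4) in GFP4. That of Gapdh was lowest in GFP0 and averaged 5.15, 5.53, 5.63, 6.34 and 5.80 from GFP0 to GFP4 (SD 0.44, 0.86, 0.19, 0.34 and 0.54; n = 2, 3, 3, 2 and 4).

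The comparison of GFP4 with GFP0 set the LSK cells that had retained the label against those that had diluted it most. Among genes expressed in HSCs, Procr (the protein C receptor) averaged 11.24 ± 0.29 (SD, n = 4) in GFP4 and 8.42 ± 0.01 (SD, n = 2) in GFP0, a difference of 2.82 ± 0.50 (SE, adjusted p = 0.0163). Mllt3 rose by 2.99 ± 0.32 (SE, adjusted p = 0.00122), and Hlf, a transcription factor of HSCs, by 2.77 ± 0.43 (SE, adjusted p = 0.0092). Cd48, a surface marker of progenitors, fell from 10.44 ± 0.11 (SD, n = 2) in GFP0 to 6.68 ± 1.37 (SD, n = 4) in GFP4 (difference -3.76 ± 0.66, SE, adjusted p = 0.015). Il7r, the interleukin 7 receptor of lymphoid cells, fell by 3.07 (SE 0.43, adjusted p = 0.00556). In all, 306 genes passed in limma after Benjamini-Hochberg adjustment, 228 higher and 78 lower in GFP4.

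The 10 genes with the highest fold under the fixed rule were Unc45b (4.11), Zfp612 (3.56), Pkp2 (3.26), Gimap8 (3.10), Gbp8 (3.00), Mllt3 (2.99), Fstl1 (2.82), Procr (2.82), Hlf (2.77) and Alcam (2.66). Gimap8 and Gbp8 encode GTPases of immune cells, and Alcam encodes an adhesion molecule. The rule asked only the brighter group to reach the table median of 7.03. In GFP0 the values of Unc45b, Zfp612, Pkp2, Gbp8 and Fstl1 lay between 4.67 and 5.85. Their folds, slopes and order thus depend on dim values without detection calls. The 10 with the lowest were Bex6 (-4.51), Clec4d (-4.05), Cd48 (-3.76), Hspa1a (-3.74), Vpreb1 (-3.55), Lrr1 (-3.37), Cd244a (-3.11), Il7r (-3.07), Ltf (-2.99) and Dscc1 (-2.83). Hspa1a encodes an inducible heat shock protein, Vpreb1 the surrogate light chain of pre-B cells, Ltf the lactoferrin of neutrophil granules and Dscc1 a DNA replication factor. The 4 GFP4 and 2 GFP0 arrays did not overlap for any of these 20 genes, as the rule required. Without GFP0 replicate 1 the differences of Alcam, Vpreb1 and Ltf were 1.68, -2.19 and -1.87 and no longer passed, and without GFP0 replicate 2 that of Hspa1a was -2.40 and passed.

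Of the 27 measured HSC markers, 16 rose in GFP4 against GFP0, none fell and 11 did not pass (20 higher adjusted over the list alone). Their median difference was 1.46 (camera adjusted p = 1.19e-23; adjusted p = 0.0814 with an estimated correlation). Of 19 multipotent and lymphoid progenitor genes, 3 fell (Cd48, Il7r and Dntt, the terminal transferase, at -3.09 ± 0.51, SE) and 16 did not pass (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.0814 with an estimated correlation). Their median of -0.49 was -1.08 without GFP0 replicate 2. S phase genes had a median of -1.04, with 2 of 25 lower, Cdt1 (-2.07 ± 0.25, SE, adjusted p = 0.00347) and Rrm2 (-2.28 ± 0.47, SE, adjusted p = 0.032). Adjusted over the list alone, 16 were lower (camera adjusted p = 1.79e-12; adjusted p = 0.133 with an estimated correlation). None of 31 G2 and M phase genes passed (1 lower adjusted over the list alone), and their median was -0.92 (camera adjusted p = 6.1e-08; adjusted p = 0.244 with an estimated correlation). Without GFP0 replicate 2 that median was -0.34 (camera adjusted p = 0.22). No list of this contrast held its camera call with an estimated correlation.

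The count of 306 was 51 without GFP0 replicate 1 (27 higher and 24 lower), 167 without GFP0 replicate 2, 185 without either GFP3 array and 118 without GFP4 replicate 4. It was 2 with array quality weights, 58 with the arrays of GFP0 and GFP4 alone, and, in alternatives chosen after seeing the data, 142 with the 3 prime to 5 prime differences as covariates, 41 without the GFP0 and GFP4 arrays numbered 1 (16 higher and 25 lower) and 112 without these and GFP4 replicate 2 (55 higher and 57 lower).

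**Figure D1:**
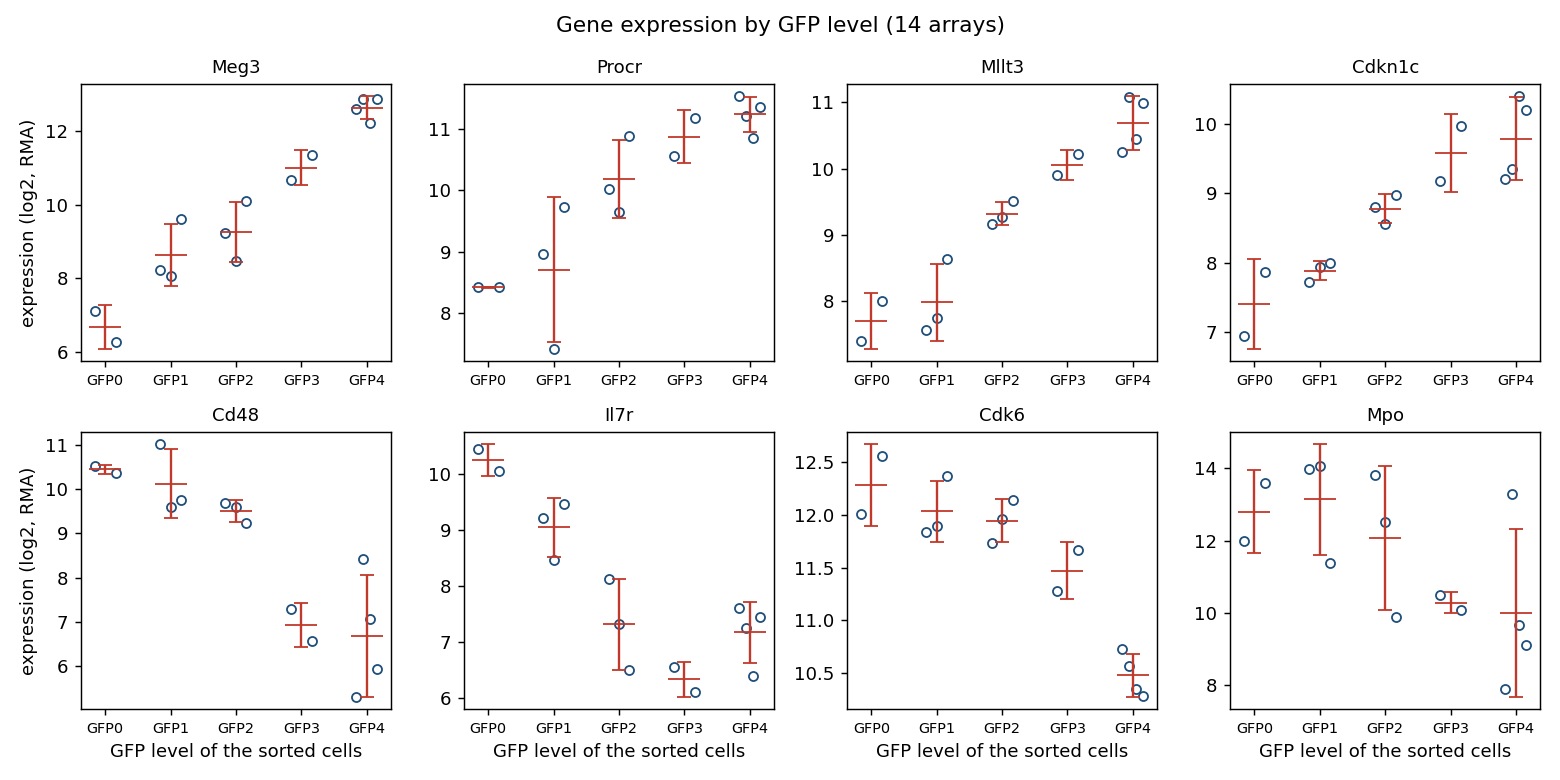
Expression (log2) of 8 genes in the 14 arrays by GFP level; each circle is an array, and the red line and bar give the group mean ± SD. Meg3, read by the steepest of its probe sets, averaged 6.68 in GFP0 and 12.64 in GFP4. Cd48 averaged 10.44 and 6.68, and Mpo of the GFP4 arrays was highest in replicate 2.

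The linear contrast over the 5 levels asked which genes rose or fell with divisional history. A change at a single level can also pass it, so a slope need not mean a steady change. Meg3, a maternally expressed noncoding RNA, had the steepest rise among the list members named, from 6.68 ± 0.60 (SD, n = 2) in GFP0 to 12.64 ± 0.31 (SD, n = 4) in GFP4 (1.43 ± 0.11 per level, SE, adjusted p = 7.36e-05). The probe set read here ends in _x_at, the kind that the rule for the steepest genes leaves out, and is the steepest of 11 for Meg3. Of these 11, 4 passed upwards, with slopes of 1.43, 0.98, 0.75 and 0.36. The other 7 did not pass, with slopes from -0.09 to 0.15. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose by 0.65 ± 0.08 per level (SE, adjusted p = 0.00177). Cdk6, a kinase of G1 progression, fell from 12.28 ± 0.39 (SD, n = 2) to 10.48 ± 0.20 (SD, n = 4), with a slope of -0.42 ± 0.05 (SE, adjusted p = 0.00177). In limma, 609 genes passed, 414 higher and 195 lower with GFP level.

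The 8 steepest rises under the rule were those of Unc45b (1.05), Zfp612 (0.92), Pkp2 (0.89), Gimap8 (0.85), Gbp8 (0.83), Mllt3 (0.81), Procr (0.78) and Fstl1 (0.78). The 8 steepest falls were those of Bex6 (-1.12), Cd48 (-1.07), Cpa3 (-0.92), Clec4d (-0.90), Lrr1 (-0.82), Vpreb1 (-0.80), Cd244a (-0.78) and Vmn2r84 (-0.67). Cpa3 encodes a carboxypeptidase of mast cells. Without GFP0 replicate 1 the slope of Vpreb1 was -0.53, that of Ltf -0.40 and that of Alcam 0.37, and without GFP0 replicate 2 the slopes of Hspa1a, Klf1 and Egr2 were -0.48, -0.43 and -0.18; of these 6, Hspa1a alone still passed. Of the genes fixed in advance, Kit (0.24 ± 0.09, SE, adjusted p = 0.178), Slamf1 (0.15 ± 0.04, SE, adjusted p = 0.0815), Flt3 (0.05 ± 0.08, SE, adjusted p = 0.779), Cd34 (-0.10 ± 0.09, SE, adjusted p = 0.624) and Mki67 (-0.31 ± 0.14, SE, adjusted p = 0.261) did not pass. Vwf (0.60 ± 0.17, SE, adjusted p = 0.0813) and Mpo (-0.85 ± 0.30, SE, adjusted p = 0.161) did not pass either, nor did Ezh1 (0.19 ± 0.05, SE, adjusted p = 0.0644). Among the named genes that passed the slope test, Meg3, Ndn, Dnmt3a, Smad3, Cdt1, Fancd2, Grb10, Ighm and Mycn each had at least 1 other probe set with a slope of the opposite sign, between -0.11 and 0.08, none of which passed.

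HSC markers rose with GFP level: 18 of 27 were higher, none lower and 9 did not pass (23 higher adjusted over the list alone). The median slope was 0.42 (camera adjusted p = 2.23e-28; adjusted p = 0.0241 with an estimated correlation). Examples were Mllt3, Ndn (0.87 ± 0.07, SE), Sult1a1 (0.70 ± 0.08, SE) and Pdzk1ip1 (0.57 ± 0.06, SE). Multipotent and lymphoid progenitor genes fell, with 8 of 19 lower, none higher and 11 that did not pass (10 lower and 1 higher adjusted over the list alone). Examples were Cd48, Il7r (-0.88 ± 0.10, SE), Dntt (-0.81 ± 0.12, SE) and Satb1 (-0.62 ± 0.12, SE), with a median slope of -0.18 (camera adjusted p = 7.51e-06; adjusted p = 0.0241 with an estimated correlation).

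Of 25 S phase genes, 7 fell and 18 did not pass (18 lower adjusted over the list alone). Cdt1, which licenses replication origins, had a slope of -0.44 ± 0.06 (SE), Rrm2 of -0.52 ± 0.11 (SE) and Mcm10 of -0.31 ± 0.08 (SE). The list median was -0.26 (camera adjusted p = 1.57e-12; adjusted p = 0.12 with an estimated correlation). Among 31 G2 and M phase genes 1 fell, Cks2 (-0.33 ± 0.08, SE), and 6 were lower adjusted over the list alone. The median was -0.23 (camera adjusted p = 1.91e-09; adjusted p = 0.253 with an estimated correlation), and -0.14 without GFP0 replicate 2. DNA repair genes had 4 of 23 lower, among them Lig4 (-0.37 ± 0.06, SE) and Fancd2 (-0.24 ± 0.05, SE), and 10 lower adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). Of 25 G1 regulators and CDK inhibitors, Cdkn1c rose and Cdk6, Ccne2 (-0.46 ± 0.09, SE) and Cdkn1a (-0.25 ± 0.05, SE) fell, and the list did not pass camera (adjusted p = 0.249). Adjusted over the list alone, 3 were higher and 4 lower.

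Interferon response genes had 4 of 17 members higher and none lower (6 higher adjusted over the list alone). They were Iigp1 (0.69 ± 0.10, SE), Ifit1 (0.39 ± 0.07, SE), Gbp2 (0.38 ± 0.08, SE) and Oasl2 (0.30 ± 0.07, SE). The median slope was 0.16 (camera adjusted p = 3.34e-06; adjusted p = 0.12 with an estimated correlation), and 0.10 without GFP0 replicate 1. Of 19 imprinted genes, 5 rose, including Meg3, Ndn, Cdkn1c and Grb10 (0.36 ± 0.05, SE), none fell and 14 did not pass (6 higher adjusted over the list alone; camera adjusted p = 0.000195; adjusted p = 0.139 with an estimated correlation). Their median slope of 0.03, under a mean of 0.21, ranged from 0.02 to 0.09 when single arrays were left out. Of 22 TGF-beta and BMP pathway genes, Ltbp3 (0.43 ± 0.08, SE) and Smad3 (0.27 ± 0.06, SE) rose, and these 2 also passed adjusted over the list alone (camera adjusted p = 0.0088; adjusted p = 0.12 with an estimated correlation).

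Myeloid progenitor genes had 2 of 17 lower, Cst7 (-1.07 ± 0.23, SE) and Plac8 (-0.52 ± 0.11, SE), with 9 lower and 2 higher adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). Of 22 megakaryocyte and erythroid progenitor genes, Car1, Klf1 and Gata1 (-0.55 ± 0.10, SE) fell and Nfe2 (0.33 ± 0.05, SE) rose (7 lower and 3 higher adjusted over the list alone; adjusted p = 0.261 with an estimated correlation). Immediate early and heat shock genes had Hspa1a and Egr2 lower of 22, and the same number adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). Ribosome biogenesis and Myc-linked genes had a median slope of -0.11 (adjusted p = 0.253 with an estimated correlation), although the 1 member of 20 that passed, Mycn (0.54 ± 0.08, SE), rose; it also passed adjusted over the list alone. Among 19 oxidative phosphorylation genes Ndufa9 fell (-0.26 ± 0.06, SE), the 1 member that also passed adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). Niche receptor and adhesion genes had 3 of 21 higher, among them Alcam and Itga6 (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.209). Of 23 chromatin regulators Dnmt3a rose (0.39 ± 0.08, SE) and Satb1 fell (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.136). Sesn2 rose and Cdkn1a fell among 18 p53 pathway genes (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.757). Without GFP0 replicate 2 camera no longer called the megakaryocyte and erythroid progenitor genes (adjusted p = 0.786; 0.0741 without GFP4 replicate 1), the immediate early and heat shock genes (adjusted p = 0.113; 0.057 without GFP4 replicate 2), the ribosome biogenesis genes (adjusted p = 0.423) or the oxidative phosphorylation genes (adjusted p = 0.0718). None of 18 glycolysis and hypoxia genes passed in either adjustment (camera adjusted p = 0.513).

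Markers of other cells that a sort could carry along also moved with GFP level. Whether the mast cell, T cell and NK cell genes were expressed in such cells or in the LSK cells themselves was not tested. Mast cell and basophil genes had 3 of 12 lower (4 adjusted over the list alone): Cpa3, Ms4a2 (-0.93 ± 0.19, SE) and Fcer1a (-0.63 ± 0.16, SE), at adjusted p = 0.16 with an estimated correlation. Of 14 B and plasma cell genes, Vpreb1 and Ighm (-0.87 ± 0.19, SE) fell (3 lower adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). Among 18 genes of neutrophils, monocytes and macrophages Ltf fell (-0.63 ± 0.14, SE), and 4 were lower adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). The mean of that list was 9.28 ± 0.98 (SD, n = 2) in GFP0 and 7.88 ± 0.57 (SD, n = 4) in GFP4. Nkg7 fell among 13 T and NK cell genes (-0.81 ± 0.18, SE), with 5 lower adjusted over the list alone (adjusted p = 0.253 with an estimated correlation). Without GFP0 replicate 1 the camera adjusted p of the slope was 0.108 for the B and plasma cell genes and 0.366 for the T and NK cell genes. No erythroblast gene (of 10), no endothelial or stromal gene (of 15) and no sex-linked gene (of 4) passed, over all genes or adjusted over the list alone. Camera called none of the 3 lists (camera adjusted p = 0.757, 0.757 and 0.808), with the sex-linked genes directed up at a median of -0.04. That list pools Xist with Y-linked genes, which would move opposite ways if the mix of sexes differed, so camera cannot judge that mix. Over the 14 arrays Xist lay between 11.2 and 13.4. The Y-linked Eif2s3y lay between 7.35 and 9.77, Uty between 6.02 and 9.34 and Kdm5d between 3.96 and 8.38.

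The count of 609 was 193 without GFP0 replicate 1 (110 higher and 83 lower), 374 without GFP0 replicate 2, 399 without GFP3 replicate 1, 182 without GFP3 replicate 2 and 283 without GFP4 replicate 4. It was 90 with array quality weights, and, in alternatives chosen after seeing the data, 165 with the 3 prime to 5 prime differences as covariates, 156 without the GFP0 and GFP4 arrays numbered 1 (88 higher and 68 lower) and 269 without these and GFP4 replicate 2 (148 higher and 121 lower).

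**Figure D2:**
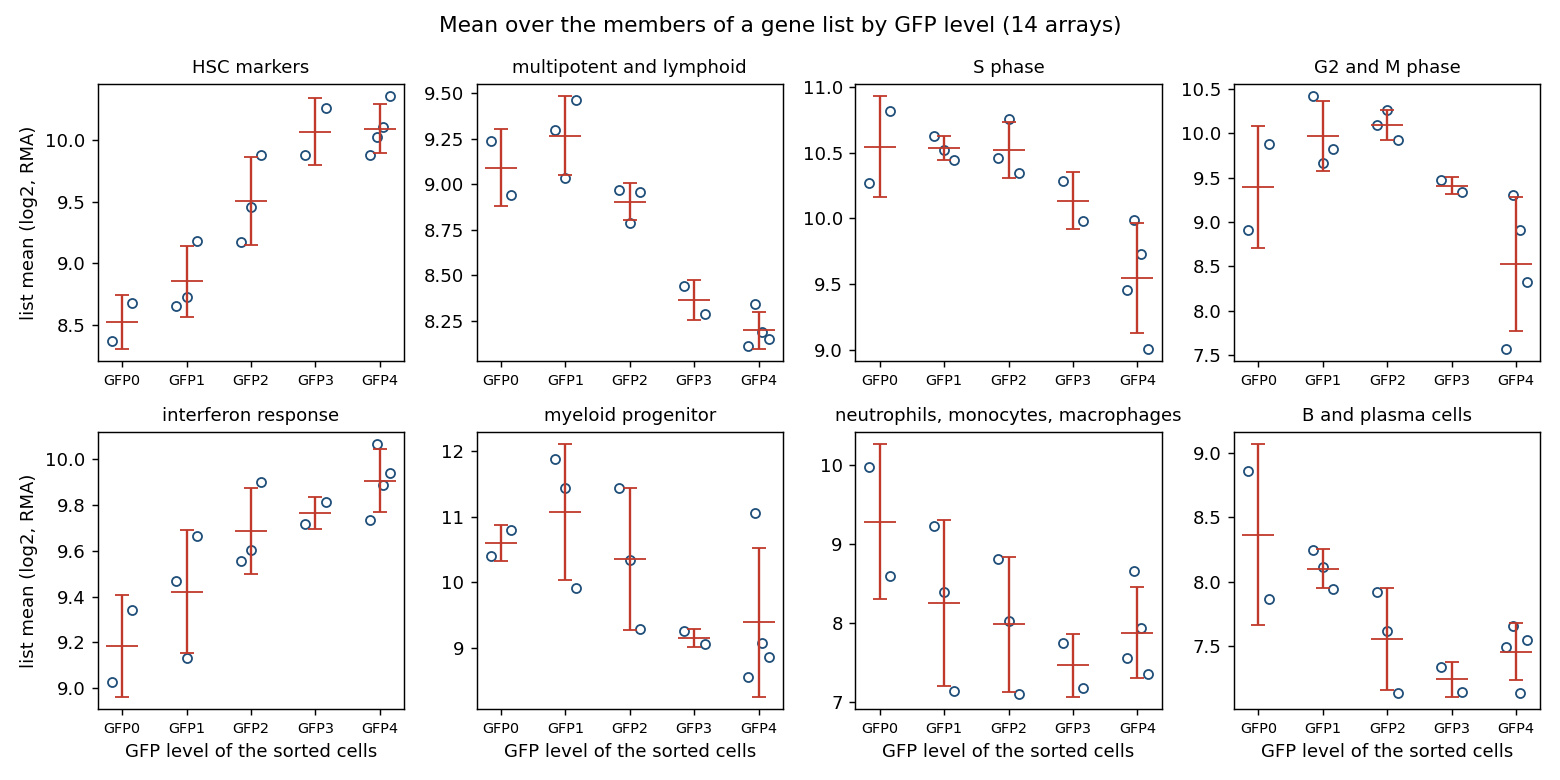
Mean log2 expression over the members of 8 gene lists in the 14 arrays by GFP level; each circle is an array, and the red line and bar give the group mean ± SD. HSC markers averaged 8.53 in GFP0 and 10.09 in GFP4, and G2 and M phase genes 9.39 in GFP0, 10.09 in GFP2 and 8.53 in GFP4.

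**Figure D3:**
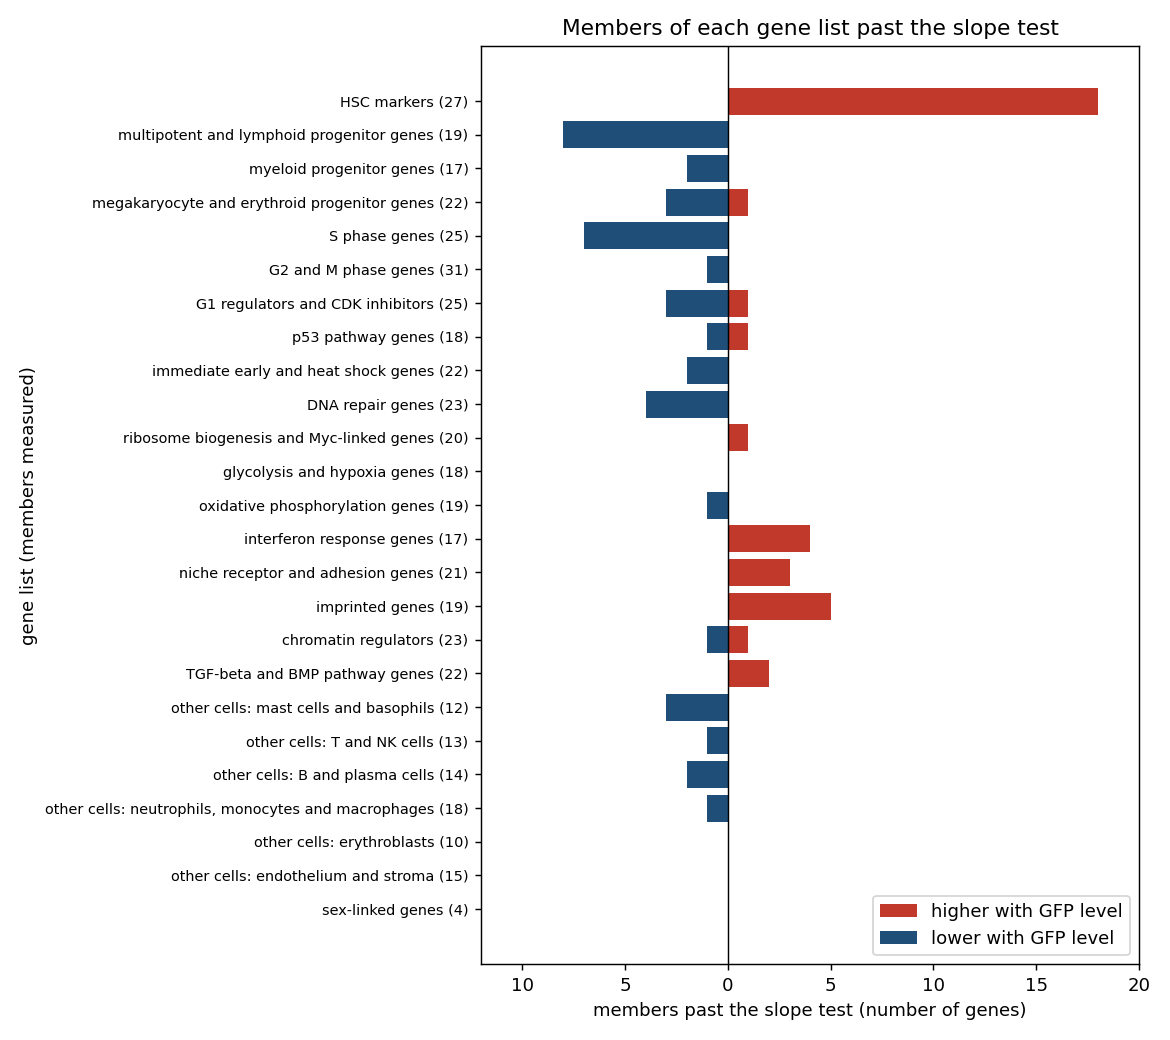
Number of members of each of the 25 gene lists past the slope test, higher with GFP level to the right and lower to the left, with the number measured in parentheses. HSC markers had 18 members higher, and multipotent and lymphoid progenitor genes had 8 lower.

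The 4 single steps asked where along the levels the changes lay. No gene passed in limma at any step. At an unadjusted p under 0.05 lay 1969 genes for GFP1 against GFP0, 493 for GFP2 against GFP1, 247 for GFP3 against GFP2 and 716 for GFP4 against GFP3. Chance alone would put a share of 0.05 of the 18194 genes there, which is more than the count of every step but that to GFP1. That excess depended on GFP0 replicate 1 and was absent without it. HSC markers were higher in camera at the step to GFP1 (median 0.28, camera adjusted p = 0.0148, and adjusted p = 0.586 with an estimated correlation). This call ended without GFP0 replicate 1 and without GFP1 replicate 3 (adjusted p = 0.326). With the interquartile range of each array as a covariate, chosen after seeing the data, the median was -0.10. The mean of immediate early and heat shock genes moved at this step too, from 9.18 ± 0.18 (SD, n = 2) in GFP0 to 8.27 ± 0.21 (SD, n = 3) in GFP1. HSC markers were also higher at the step to GFP2 (median 0.62, and 0.36 without GFP2 replicate 3, adjusted p = 0.122 with an estimated correlation). The same held at the step to GFP3 (median 0.52, adjusted p = 0.156 with an estimated correlation). At the step to GFP4 their median was -0.06 (camera adjusted p = 0.879). Multipotent and lymphoid progenitor genes were lower in camera at the step to GFP2 (median -0.25, camera adjusted p = 0.00151, and 0.192 without GFP1 replicate 3; adjusted p = 0.122 with an estimated correlation) and at that to GFP3 (median -0.54, adjusted p = 0.0204 with an estimated correlation). G2 and M phase genes had a median of 0.53 at the step to GFP1 (adjusted p = 0.586 with an estimated correlation; 0.04 without GFP0 replicate 1), of -0.75 at that to GFP3 (adjusted p = 0.209 with an estimated correlation) and of -0.88 at that to GFP4 (adjusted p = 0.216 with an estimated correlation; -0.55 without GFP4 replicate 1). S phase genes had medians of -0.36 and -0.63 at the steps to GFP3 and GFP4 (adjusted p = 0.209 and adjusted p = 0.209 with an estimated correlation). With array quality weights 2 genes passed for GFP4 against GFP3.

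The overall test over the levels asked for a difference of any shape. In limma, 127 genes passed, among them Meg3 (adjusted p = 0.00113), Gbp8 (adjusted p = 0.00113), Mllt3 (adjusted p = 0.00229) and Cdt1 (adjusted p = 0.00472). Cdt1 averaged between 10.81 and 11.20 in GFP0 to GFP3 and 9.13 ± 0.38 (SD, n = 4) in GFP4. No gene passed for a departure from a straight line, with 1275 at an unadjusted p under 0.05, and fewer without GFP0 replicate 1. The 6 genes with the smallest p there were Hspa1a, Sh2d5, Iqgap3, Lims1, Mlec and Odf2 (adjusted p = 0.679 for each); Lims1 averaged 12.04 in GFP1 and in GFP2, 10.55 in GFP0 and 10.52 in GFP4. The count of 127 was 59 without GFP0 replicate 1, 77 and 50 without GFP2 replicates 1 and 2, 64 and 37 without GFP3 replicates 1 and 2, and 44, 45 and 28 without GFP4 replicates 1, 3 and 4. It was 335 with array quality weights, 38 with arrays centred on their medians, and, in an alternative chosen after seeing the data, 11 with the 3 prime to 5 prime differences as covariates.

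The last contrast set the step from GFP3 to GFP4 against the step from GFP0 to GFP1, which share no array. G2 and M phase genes differed with a median of -1.41, all 31 members below 0 (camera adjusted p = 1.04e-11; adjusted p = 0.455 with an estimated correlation), and -0.88 without GFP0 replicate 1. No gene passed in limma, with 2584 at an unadjusted p under 0.05, and fewer without GFP0 replicate 1.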

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

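The tests of a wrong GFP level and of admixture for GFP4 replicate 2 were chosen only after its values had been seen; the covariates of the RNA quality test were also chosen after seeing the data, with its bound set before its result, and the other tests of this part were planned before their results.

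Among 147 named genes and list means, 8 had a GFP4 array far from the other 3, where chance marks about 1 in 20, or 7.35. In GFP4 replicate 2, Cpa3 was 9.77 against a mean of 6.50, Dntt 12.38 against 10.11 and Ezh1 11.06 against 10.39. In GFP4 replicate 1, Dcn was 7.28 against 6.70, Itga6 9.02 against 9.92, Jun 8.98 against 8.55 and Ldha 10.56 against 11.15. In GFP4 replicate 3, Ltbp3 was 11.68 against 12.23.

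GFP4 replicate 2 stood apart from the other GFP4 arrays, with Mpo at 13.3 against 7.9, 9.7 and 9.1. A wrong label was tested through 19 HSC markers placed between GFP0 (0) and the other GFP4 arrays (1). The median was 0.899 in this array, 0.260 in GFP1, 0.592 in GFP2 and 0.886 in GFP3, which argues against a GFP0 or GFP1 sample. Against a GFP2 sample it argues less clearly, since GFP2 was read as a group. In the mean of all HSC markers GFP2 replicate 3 reached 9.88, as did GFP4 replicate 1, against 10.03 in this array. Over 655 genes with an unadjusted p under 0.05 for GFP4 against GFP3 the array lay at 0.613 between both, where held-out GFP3 arrays lay at 0.266 and 0.429 and other GFP4 arrays at 0.301 to 0.747, so a GFP3 sample cannot be told apart by this overlapping measure, although Meg3 (12.86) and Cdt1 (8.81) were as in GFP4 and the myeloid progenitor mean (11.06) exceeded both GFP3 arrays (9.25 and 9.05). Admixture of less labelled LSK cells would need a share of 0.950 for Mpo. The median over 278 genes that fall with GFP level was 0.336. This is under the bound of 0.475 set for the test, but the upper quartile of 0.710 is not, so the test left admixture open. A share of 0.950 would put the 19 HSC markers close to GFP0 (0) and GFP1 (0.260), but they lay at 0.899 (quartiles 0.759 and 1.02). That argues against average less labelled cells as the whole cause of the Mpo value, while a smaller share stays open. Little labelled target could not be settled either: over the other 13 arrays the spikes and the myeloid progenitor genes deviated together with r = 0.362 (permutation p = 0.226; rho = 0.440, permutation p = 0.133; r = 0.371 without the 2 farthest arrays), and no biological explanation was tested, since the design names none within a group.

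S phase and G2 and M phase genes were lower with GFP level by camera (adjusted p = 0.12 and adjusted p = 0.253 with an estimated correlation), with 7 of 25 and 1 of 31 members past the test. With the 3 prime to 5 prime differences as covariates the median slope of the S phase genes was -0.18 against -0.26 before, and camera at the preset correlation still passed, which argues against RNA quality as the whole cause. Without each GFP4 array in turn the smaller share of the median slope kept by either list was 0.819, which argues against a single GFP4 array. The number of divisions, which the design names, remains open as a hypothesis, as do other explanations not tested here, technical or biological. HSC markers rose and multipotent and lymphoid progenitor genes fell over the same levels, and the mix of cells in each gate was not tested. The number of divisions may not act evenly, since G2 and M phase genes averaged 9.39 in GFP0 and 10.09 in GFP2. Their slope rests in part on GFP0 replicate 2 (0.819 covers the GFP4 arrays alone).

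Lists of genes of neutrophils, monocytes and macrophages and of B and plasma cells were lower with GFP level by camera (adjusted p = 0.253 and adjusted p = 0.24 with an estimated correlation), with 1 of 18 and 2 of 14 members past the test. Mature neutrophils carried into the low GFP gates may account for the fall of Ltf (-2.99 from GFP0 to GFP4): S100a8, S100a9, Ngp, Camp and Lcn2 had a median difference of -3.68, although none of the 5 passed and GFP0 replicate 1 was the highest array for each of Ngp, Camp, Lcn2 and Ltf, without which the difference of Ltf was -1.87 and did not pass. The lineage gate of the sort would remove such cells, and early myeloid cells with these transcripts were not told from mature ones. A large carry-over of mature B cells is argued against, since Cd79a, Cd79b, Ms4a1, Cd22, Fcer2a and Cr2 had a median difference of -0.31. The difference of Vpreb1 was -3.55 (-2.19 without GFP0 replicate 1). Vpreb1 is a gene of pre-B cells, so a comparison with it does not test mature B cells, and early B cells were not tested.

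The step from GFP3 to GFP4 differed from the step from GFP0 to GFP1 in 8 lists by camera on the difference itself. Medians of the difference were -1.41 for G2 and M phase genes, -0.64 for S phase genes, -0.51 for ribosome biogenesis and Myc-linked genes, -0.48 for glycolysis and hypoxia genes, -0.45 for chromatin regulators and -0.36 for DNA repair genes. They were 0.58 for immediate early and heat shock genes and 1.06 for genes of neutrophils, monocytes and macrophages. None of the 8 held with an estimated correlation (adjusted p = 0.461 for ribosome biogenesis, adjusted p = 0.49 for the list of neutrophils and adjusted p = 0.455 for each of the other 6). Without GFP0 replicate 1 the medians were -0.88 (G2 and M phase), -0.35 (S phase), -0.32 (glycolysis), -0.24 (ribosome biogenesis), -0.11 (chromatin), -0.02 (DNA repair) and 0.78 (neutrophils), and camera no longer called the last 4. Without GFP0 replicate 2 those of glycolysis, ribosome biogenesis and DNA repair genes were -0.77, -0.84 and -0.79. The calls also ended without GFP3 replicate 1 for ribosome biogenesis, chromatin and DNA repair genes, without GFP1 replicate 1 or GFP4 replicate 4 for ribosome biogenesis and without GFP1 replicate 3 for chromatin regulators.

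Chance assignments of the arrays to levels were drawn for the counts. For the slope, 3 of 100 assignments, the real one included, gave at least the real 609 genes, and the highest of the others gave 3798. For any difference, 4 of 100 gave at least the real 127, and the highest other gave 2211. Both shares lay under the bound of 0.05 set for the test, but too near it for 100 draws to exclude chance. Assignments with several times the real count point to a structure of the samples beyond the levels. The count for GFP4 against GFP0 was not tested in this way. For GFP2 against GFP1 the 10 splits of 6 arrays are too few for a share under 0.05; at an unadjusted p under 0.05 the real split gave 493 genes, 5 splits gave at least as many, and the highest other gave 2110.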

How the results depend on the processing

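Leaving out several arrays and the covariates were chosen after seeing the data, and the cause was not tested for any value below; of 108 named-gene results that passed, all 108 kept their direction under every setting, and 37 passed without any single array. Those 108 results had been picked as passing in these same arrays, so their kept direction is weak evidence. Array quality weights gave 2 genes for GFP4 against GFP0, 90 for the slope, 2 for GFP4 against GFP3 and 335 for any difference. Arrays centred on their medians gave 38 for any difference, and the arrays of both groups alone gave 58 for GFP4 against GFP0. Whether replicate numbers pair the arrays stays open, and the arrays were treated as unpaired. In deviations from the group means, 9 of 23 same-numbered pairs of arrays from different groups correlated with r over 0.1. The median r was 0.0462 in these 23 pairs, with a highest of 0.576, and -0.0456 in differently numbered pairs. The best partner had the same number for 6 of 14 arrays. With the replicate block 67 genes passed for GFP4 against GFP0 (306 without it) and 337 for the slope (609 without it). The block gave 34 for any difference and 1 for the difference between the GFP4 and GFP1 steps. With each array left out in turn the counts were 51-363 for GFP4 against GFP0, 182-768 for the slope, 28-158 for any difference, 0-2 for GFP1 against GFP0, 0-3 for GFP2 against GFP1, 0-1 for the departure from a line and 0-1 for the difference between steps. Without the GFP0 and GFP4 arrays numbered 1 the counts were 41 (GFP4 against GFP0), 156 (slope), 20 (any difference), 2 (GFP1 against GFP0), 1 (departure) and 1 (difference between steps). Without these and GFP4 replicate 2 they were 112, 269, 38 (any difference), 2 (GFP1 against GFP0) and 2 (difference between steps). The 3 prime to 5 prime covariates gave 142 (GFP4 against GFP0), 165 (slope) and 11 (any difference), and the interquartile range gave 80 (any difference).

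The slope of Mlec turned from 0.05 to -0.20 with the mean over its probe sets. For lists, the direction of camera turned in the cases below, not always with the sign of the median. For GFP1 against GFP0, the medians of S phase and DNA repair genes (-0.07 and 0.17, both directed up and not called) lay at -0.34 to 0.19 and -0.32 to 0.46 with single arrays left out, lowest without GFP0 replicate 1, and were -0.34 and -0.32 in both settings without several arrays; camera called both lists lower in these 3 settings. The myeloid progenitor median for GFP4 against GFP3 lay at -0.20 (without GFP4 replicate 2, called lower) to 0.43, and the megakaryocyte and erythroid median for GFP3 against GFP2 was 0.11 with the 3 prime to 5 prime covariates (called higher). With the interquartile range the median was -0.10 for HSC markers in GFP1 against GFP0. With it the median of chromatin regulators shrank from 0.34 to 0.0419 in GFP1 against GFP0 and kept its sign. For chromatin regulators in the difference between the GFP4 and GFP1 steps it shrank from -0.45 to -0.0893 and kept its sign.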

Other observations

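Gene families that the fixed lists leave out were looked at after the top genes had been seen, so the families below were chosen from these data and are no independent evidence. Of 8 Gimap GTPases, a family of lymphocyte GTPases, 4 rose with GFP level: Gimap1 (0.41 ± 0.06 per level, SE), Gimap5 (0.59 ± 0.09, SE), Gimap6 (0.33 ± 0.06, SE) and Gimap8 (0.85 ± 0.09, SE). Of 12 guanylate binding proteins and immunity-related GTPases, which interferon induces, 4 rose: Gbp2, Gbp6 (0.50 ± 0.10, SE), Gbp8 (0.83 ± 0.07, SE) and Iigp1. Among 26 replication factors 7 fell, including Gins1 (-0.55 ± 0.08, SE), Orc1 (-0.23 ± 0.05, SE) and Prim1 (-0.35 ± 0.08, SE). These 3 families passed camera (adjusted p = 0.000282, 7.15e-09 and 7.15e-09), and none did with an estimated correlation (adjusted p = 0.145, adjusted p = 0.145 and adjusted p = 0.157 with an estimated correlation).

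Proteasome subunits (39 genes, median slope -0.09, adjusted p = 0.374 with an estimated correlation) and S1P, chemokine and interleukin receptors (46 genes, median slope -0.05, adjusted p = 0.374 with an estimated correlation) also passed camera. In the latter S1pr3 (-0.74 ± 0.13, SE), Ccr9 (-0.60 ± 0.13, SE) and Il7r fell and Il12rb1 (0.22 ± 0.05, SE) rose. Collagens, Hox genes, MHC class I genes, cytoplasmic ribosomal proteins, aldehyde dehydrogenases and Kruppel-like factors did not pass camera (adjusted p = 0.374, 0.374, 0.352, 0.733, 0.374 and 0.776). Single members of these passed all the same: Col4a1 (0.63 ± 0.10, SE) and Col4a2 (0.62 ± 0.11, SE), chains of basement membrane collagen, rose, as did Hoxa5 (0.44 ± 0.08, SE), Hoxb5 (0.42 ± 0.09, SE), Aldh1a1 (0.41 ± 0.10, SE) and Klf12 (0.69 ± 0.15, SE). Klf1 (-0.70 ± 0.16, SE) and Rps27l (-0.24 ± 0.06, SE) fell.

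Meg3 lies in an imprinted region with the other maternally expressed RNAs Rian and Mirg, and a hypothesis set before their values were seen was that these rise together. Of Rian and Mirg, 0 passed the slope test upwards (Rian -0.13 ± 0.06, SE, adjusted p = 0.31; Mirg 0.00 ± 0.05, SE, adjusted p = 0.991). The bound set in advance against the hypothesis was met, but after the values were seen it was judged wrong for these probe sets: 7 of the 11 Meg3 probe sets also missed the rise of Meg3. Whether the RNAs of the region rise together cannot be told apart from probe sets that miss them.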
